A study of Mus musculus with 6 samples.

How the data were processed

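Immune cells (viable, EpCAM-negative and CD45-positive) had been sorted from pooled colon tumours of mice and sequenced with the 10x Genomics 3' v3 chemistry, which tags each captured RNA molecule with a UMI and a cell barcode. There were 6 libraries, 1 Control and 1 SOX17KO library at each of 3 collections. The labels give 1 week and 2 weeks for 4 libraries and no time for the other pair, and whether that pair was collected on another day or at another age is not given in the sources used here. The deposited files hold a raw UMI count per gene and cell barcode, whole numbers without normalisation, for 32285 genes. The submitters' notes name Cell Ranger 6.0.1 and the mm10 build, while the matrix headers name Cell Ranger 7.0.1. The intron setting and the gene annotation release are not given. Only barcodes already called as cells were deposited. Positions of named genes were taken from the GENCODE annotation of mm10, matched by Ensembl identifier.

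The untimed Control and SOX17KO libraries held 6955 and 6430 barcodes, the 1-week libraries 5579 and 7495, and the 2-week libraries 4985 and 3163. Barcodes with under 200 genes (1 to 45 per library) or over 10% mitochondrial UMIs (48 to 202 per library) were removed. Doublets were scored per library by the share of simulated doublets among nearest neighbours, in the manner of Scrublet. The top 0.8% of barcodes per 1000 recovered were removed, 80 to 449 per library. The automatic threshold of that score, planned as an alternative, marked at most 0.0948% of barcodes in any library and so did not work here. Kept were 6497 and 6051 cells of the untimed pair, 5243 and 6862 at 1 week, and 4585 and 2933 at 2 weeks. Of the 210130933 UMIs in the matrices, the kept cells of the 6 libraries in that order held 38030320, 25990047, 33842417, 46366922, 25259443 and 17105852.

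Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, without immunoglobulin and T cell receptor segments, mitochondrial, ribosomal, haemoglobin and sex-linked genes, gave 30 principal components. A graph of 15 neighbours was clustered with the Leiden method at resolution 1. This gave 36 clusters, and the T cell, NK cell and ILC clusters were clustered again into 21. Clusters were named from marker lists fixed before the data were examined. The rule that turns the lists into names (a score of 1 over the other clusters, 3 markers detected in 10% of cells, and no second unrelated list at a comparable score) was set after the clusters had been seen. By this rule 8 first-level clusters and 1 subcluster stayed unnamed. The largest group of T cells is called Cd8a-expressing and not CD8, because the 10 leading genes of its largest subcluster held Tnfsf11, a CD4 list gene, and none of the CD8 list. Names rest on mRNA alone.

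Each class share was given with an exact Clopper-Pearson 95% interval. The difference between genotypes was taken as log2 odds (with 0.5 added) within each collection, and its mean over the 3 collections was tested with a two-sided exact sign-flip permutation test, whose smallest reachable p is 0.25. P values were adjusted over 14 classes. Genes were tested on counts summed per library in the 7 classes with at least 20 cells in every library. The test was edgeR's quasi-likelihood test with TMM scaling, its expression filter, and collection and genotype as terms, at a Benjamini-Hochberg adjusted p of 0.05. The 3 collections serve as replicates, so that its residual spread (2 degrees of freedom) is the disagreement of the genotype difference between collections. Within 1 collection no test was made. There, ratios of CPM were given with an exact conditional binomial 95% interval, and a gene with 0 UMIs in 1 library was set against a floor of 3 counts in that library. Readouts were the shares of cells with a UMI after thinning each cell to 1000 UMIs, with 16 readouts in the family and B cells or Cd8a-expressing T cells as the class that should lack the gene. The result of 1 readout is not reported here.

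The 18 gene lists covered interferon-gamma response, type I interferon response, MHC class I and class II presentation, cytotoxic effector genes, inhibitory receptors and exhaustion, naive and central memory, tissue residency, regulatory T effector, type 17 cytokines, chemokines, suppressive and lipid-associated macrophages, inflammatory cytokines, hypoxia and glycolysis, neutrophil maturity and aging, proliferation, dissociation stress and immediate early genes, and mitochondrially encoded genes. Of their genes 6 were not matched by symbol: Cxcl11, Mx1, Mx2, Il26, Ero1a and Aldoa. The last 2 are in the matrices, Ero1a as Ero1l and Aldoa under 2 identifiers, and so were left out of the hypoxia list by mistake. With them added, its 4 calls stayed (limma adjusted p 0.000469 to 0.0407). Each list with at least 5 members past the filter was tested with limma camera on edgeR log2 CPM (prior count 2) at a preset correlation of 0.01, with an estimated correlation and with fry beside it. Adjustment was over all 117 tests. A list's median per collection was set against 10000 random lists of matched expression.

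Samples, comparisons, tests, gene lists, markers, the rule for named genes and a first set of alternatives were fixed before the data were examined. The rule names, per class, genes past the adjusted p with the same sign in all 3 collections (up to 10 per direction). Where fewer than 10 pass, it adds up to 10 per direction with the same sign in all 3 collections and a mean of at least 50 CPM, as values without a call. Per collection and class it takes the 5 highest and 5 lowest ratios by the interval bound nearest to 1, with at least 50 UMIs in the higher library. It adds up to 4 members per list and class with a mean of at least 20 CPM, and always Sox17, Ifng, Gzmb, Cd8a, Cd274, Ifngr1, Cxcl9, Cxcl10 and H2-Ab1. Immunoglobulin and receptor segments, mitochondrial and ribosomal genes, haemoglobins, gene models, sex-linked genes and markers of another class were not named under the first 3 parts. From the genes so taken, the text names a part. Isg15 and Spp1 in the change from 1 to 2 weeks lie outside the rule and were chosen after the data had been examined, as were the unnamed clusters given by number.

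Alternatives were at least 500 genes or at most 5% mitochondrial UMIs per cell, no doublet removal or the automatic threshold, resolution 2, each collection clustered alone, other denominators of the shares, DESeq2, limma-voom, RLE size factors, no expression filter, no collection term, TMM totals for the ratios, thinning to 500 UMIs or none, and leaving out each collection. Chosen after seeing the data were counting unnamed clusters with their closest class, a denominator without fibroblasts and unnamed clusters, a test of Cd8a-expressing T cells in the untimed and 2-week pairs alone, a test of NK cells without ILCs for genes and for lists, and the hypoxia list with Ero1l and Aldoa.

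The tests were tested on simulated data made from these libraries, with 200 genes changed per class, 100 at each of 2-fold and 4-fold. edgeR recovered 65.0% to 100% of the 4-fold changes that passed the filter and 16.8% to 71.4% of the 2-fold changes, depending on the class, with 6 to 31 false calls per class. The ratio interval held the true ratio in 96.1% of 3000 simulated pairs, which were Poisson draws that used no library. The interval covers such pairs by construction, so this checks the computation alone. It says nothing about genes whose UMIs lie in few cells. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.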

Results

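Single-cell RNA sequencing was done on immune cells sorted from mouse colon tumours of 2 genotypes, Control and SOX17KO, the second named for loss of the transcription factor SOX17. The sort took viable cells (negative for the dye 7-AAD) that carried the leukocyte antigen CD45 and lacked the epithelial antigen EpCAM. It was thus meant to leave the tumour cells out, though a cluster with few UMIs per cell had epithelial keratin genes among its leading genes. There were 6 libraries in 3 collections, each with 1 Control and 1 SOX17KO library: a pair whose labels give no time (the untimed pair), a 1-week pair and a 2-week pair. According to the series description, tumours of 5 mice were pooled per condition; whether this held at each time is not given in the sources used here. The matrices held 34607 cell barcodes. Their totals were 45533699 unique molecular identifiers (UMIs) in the untimed Control and 29086439 in the untimed SOX17KO library. At 1 week the totals were 37262312 and 52150180, and at 2 weeks 27816981 and 18281322. After filtering, 32171 cells were kept, between 2933 and 6862 per library, with a median of 3009 to 5910 UMIs per cell. Each combination of genotype and collection was 1 library. There is therefore no replicate check within a collection, and intervals given for 1 library or 1 pair are 95% and cover counting error only.

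The first question was which immune cells made up the tumours of each genotype. The clearest differences were in the untimed and 2-week pairs, and for T cells they ran in opposite directions. In the untimed pair T cells were 55.1% of Control cells [53.9, 56.3] and 74.6% of SOX17KO cells [73.4, 75.6]. In the 2-week pair they were 46.2% and 26.2%, and at 1 week, when the tumours held mainly monocytes and macrophages, 1.32% and 1.88%. Neutrophils were lower in the untimed SOX17KO library, at 0.215% against 5.53%, and higher in the SOX17KO library at 1 week, 10.5% against 4.73%, and at 2 weeks, 8.08% against 4.34%. Monocytes and macrophages were 3.02% of Control and 0.892% of SOX17KO cells in the untimed pair, 56.2% and 55.4% at 1 week, and 20.2% and 27.2% at 2 weeks. The direction in the untimed pair turned when each collection was clustered on its own, to a log2 odds difference of 0.23, and when unnamed clusters were counted with their closest class, to 0.61. Plasmacytoid dendritic cells, the main source of type I interferon in many viral infections, numbered 218 of the untimed Control cells and 1 of the untimed SOX17KO cells. They were not named as a class in any library without doublet removal, with the automatic doublet threshold or with each collection clustered on its own. B cells were 0.458% of Control and 6.21% of SOX17KO cells at 2 weeks. Dendritic cells of the other types were 7.02% and 3.92% in the untimed pair, 8.74% and 7.72% at 1 week, and 8.18% and 8.29% at 2 weeks.

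Of 14 classes, the only ones with the same direction in all 3 pairs were plasma cells, mast cells and fibroblasts, each higher in SOX17KO. Their mean log2 odds differences were 1.47, 0.72 and 2.06. Plasma cells numbered 56 and 103 in the untimed pair, 1 and 4 at 1 week, and 0 and 1 at 2 weeks. The 0 of 4585 Control cells allows a share of up to 0.065%, taken as 3 of 4585 cells and not as a Clopper-Pearson bound. The mean for plasma cells turned to -1.05 when unnamed clusters were counted with their closest class. The cluster so added to plasma cells held 614 Control and 59 SOX17KO cells in the untimed pair. It had epithelial keratin genes among its leading genes. Fibroblasts, which the CD45 gate should have removed, were 0.077% and 2.79% in the untimed pair, 3.09% and 3.85% at 1 week, and 2.09% and 3.48% at 2 weeks. A two-sided exact sign-flip permutation test over the 3 differences cannot give a p below 0.25. It gave 0.25 for these 3 classes, with a Benjamini-Hochberg adjusted p of 1 over the 14. An edgeR test on cells per class called none, with a lowest adjusted p of 0.661. Cells in unnamed clusters were 15.6% and 7.54% of the untimed Control and SOX17KO cells, 21.7% and 16.2% at 1 week, and 11.7% and 12.5% at 2 weeks.

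**Figure D1:**
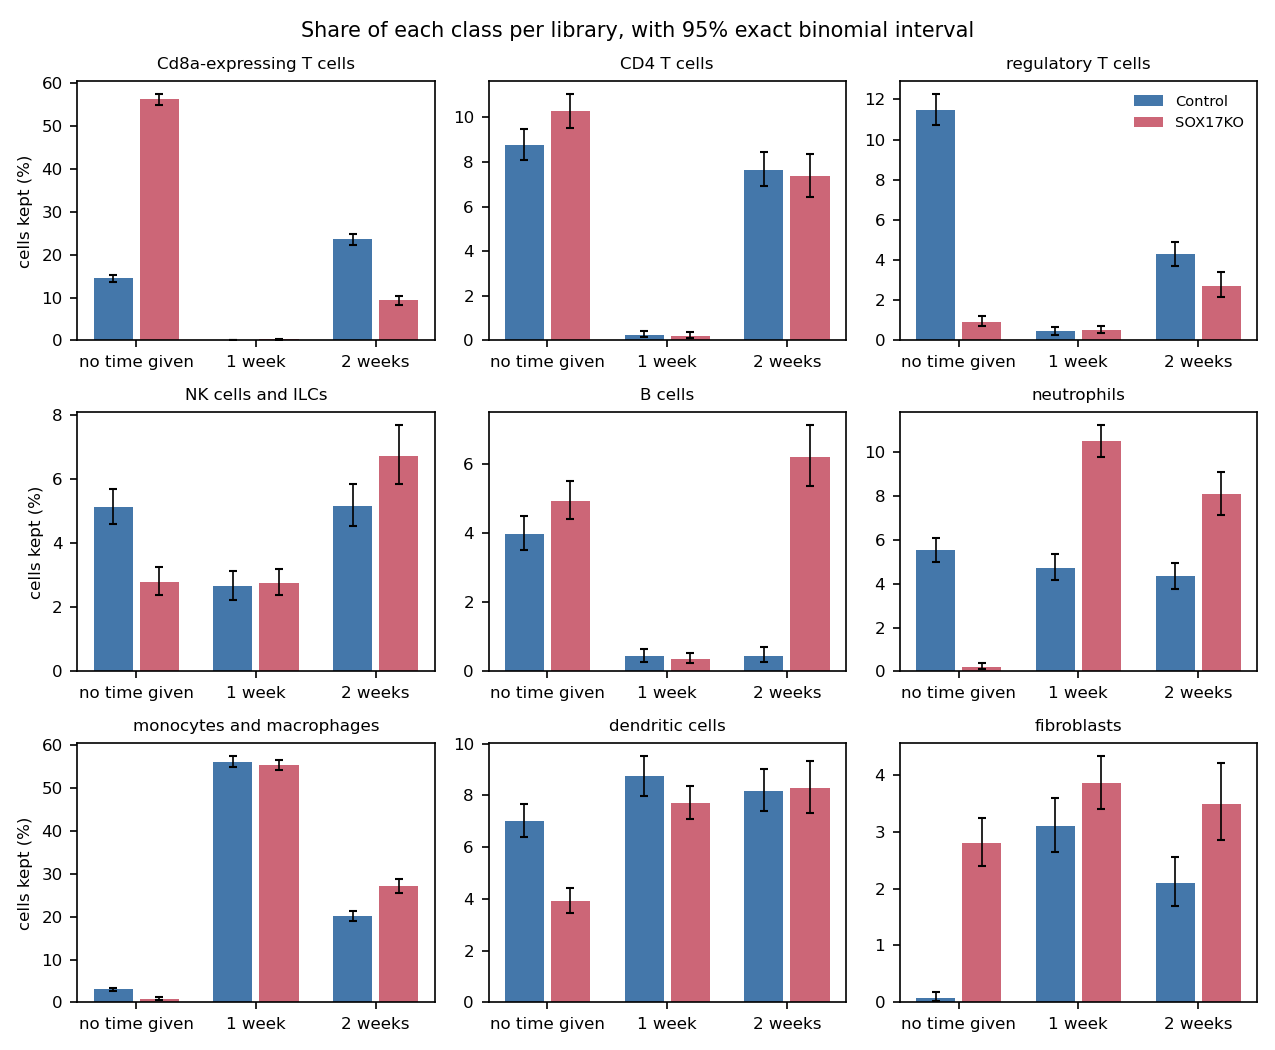
Percent of kept cells in selected classes, fibroblasts included (vertical axis), in the Control (blue) and SOX17KO (red) library of each collection. Bars carry 95% exact binomial intervals for counting error. Cd8a-expressing T cells were 14.4% and 56.2% in the pair with no time given, and 23.5% and 9.31% at 2 weeks.

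Within T cells, the untimed SOX17KO library was dominated by cells with mRNA of Cd8a, a chain of the CD8 co-receptor of cytotoxic T cells. These Cd8a-expressing T cells were 14.4% of Control cells [13.6, 15.3] and 56.2% of SOX17KO cells [54.9, 57.5], or 26.2% and 75.4% of the T cells. Regulatory T cells, defined by Foxp3 and able to restrain other T cells, were 11.5% of Control cells (746 cells) and 0.925% of SOX17KO cells (56 cells) in that pair. At 2 weeks the Cd8a-expressing share was 23.5% [22.3, 24.8] against 9.31% [8.28, 10.4], and the regulatory share 4.30% against 2.73%. Among T cells alone, however, regulatory cells were 9.31% and 10.4% at 2 weeks. Only 4 and 15 Cd8a-expressing T cells were found at 1 week. CD4 T cells were 8.74% and 10.3% in the untimed pair and 7.66% and 7.36% at 2 weeks. As a share of T cells both differences turned, with 15.9% and 13.8%, and 16.6% and 28.1%. Gamma-delta T cells were 5.23% and 3.17% in the untimed pair and 0.134% and 0.495% at 1 week. Natural killer (NK) cells were 4.77% and 1.26%, 2.58% and 2.57%, and 5.13% and 6.55% in the untimed, 1-week and 2-week pairs. Innate lymphoid cells (ILCs), which share their class with NK cells here, numbered 23 and 93, 4 and 14, and 2 and 5. The Cd8a-expressing cells of the untimed genotypes lay largely in different subclusters. Subclusters 0 and 1 held 1941 and 1224 SOX17KO cells but 5 and 45 Control cells, and subcluster 8 held 587 Control and 6 SOX17KO cells.

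The next question was which genes differed between the genotypes across the 3 pairs. In regulatory T cells, Fos, a subunit of the AP-1 transcription factor, rose in SOX17KO, with a log2 fold change of 1.75 ± 0.24 (SE, n = 3 pairs). Each SE in this paragraph was derived from the moderated edgeR F statistic and is not the spread of the 3 pair values. Pkp4, a plakophilin of cell junctions, fell by 2.41 ± 0.35, and Bmyc, a relative of the Myc transcription factor, fell by 2.05 ± 0.32. The Fos values in the untimed, 1-week and 2-week pairs were 1.61, 1.78 and 1.97, and those of Bmyc -2.20, -2.08 and -1.66. Those of Pkp4 lay furthest apart, at -2.75, -0.20 and -1.89. In the class of NK cells and ILCs, 6 genes rose and none fell. Areg, the epidermal growth factor family member amphiregulin, rose by 1.98 ± 0.25, and Hlf, a transcription factor of the PAR bZIP family, by 2.96 ± 0.37. The others were Pard3, a cell polarity gene (2.66 ± 0.28), Ube2e2, a ubiquitin-conjugating enzyme (2.55 ± 0.29), Plcl1 (2.42 ± 0.31) and the sphingomyelin synthase gene Sgms1 (2.36 ± 0.27). ILCs were 23 of 333 Control and 93 of 169 SOX17KO cells of this class in the untimed pair. They were 4 of 139 and 14 of 190 at 1 week, and 2 of 237 and 5 of 197 at 2 weeks. The ILC share of the class was thus higher in SOX17KO in each pair, and these rises cannot be read as a change within NK cells. Areg was on the ILC marker list. Of the 6 genes, Pard3 was among the 10 leading genes of the ILC subcluster, and the other 5 were not. In NK cells alone 5 of the 6 genes did not pass the expression filter, Areg had a log2 fold change of -0.08 ± 0.43 and an edgeR adjusted p of 0.992, and no gene was called (397 at an unadjusted p under 0.05). The test was the edgeR quasi-likelihood test on counts summed per library, with collection as a term and 2 residual degrees of freedom. Adjusted p values from edgeR were 0.0154 for Fos, 0.0264 for Pkp4 and Bmyc, and 0.0205 to 0.0225 for the 6 genes of NK cells and ILCs. Without the 1-week pair, or without the 2-week pair, no gene was called in NK cells and ILCs. With 1 pair left out, calls ranged up to 34 in that class and from 5 to 23 in regulatory T cells. Where fitted with 1 pair left out, the log2 fold changes of the 6 genes were at least 1.55. None was called in regulatory T cells when cells above 5% mitochondrial UMIs were left out, nor in either class without collection as a term.

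Where edgeR called no gene, other tools differed. In all cells summed, edgeR called 0 of 15756 genes (798 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 39. In T cells the counts were 0 of 12111 (945), 0 and 6, and in dendritic cells 0 of 10545 (794), 0 and 1. B cells gave 0 of 5417 (258) with edgeR, 10 with limma-voom and 0 with DESeq2. Monocytes and macrophages gave 0 of 10057 (219) with edgeR and 0 with both others. For regulatory T cells limma-voom called 6 genes and DESeq2 2, and for NK cells and ILCs these tools called 6 and 8. Cd8a-expressing T cells could be tested only in the untimed and 2-week pairs, where edgeR called 0 of 11611 genes (867 at an unadjusted p under 0.05). Leaving out the untimed pair gave 20 genes in all cells, and leaving out the 2-week pair gave 114 in T cells. With 1 pair left out, up to 53 were called in B cells and up to 17 in monocytes and macrophages.

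Some genes had the same direction in all 3 pairs without passing the test, and are given as log2 ratios of the untimed, 1-week and 2-week pairs. Over all cells, in sums that follow class shares too, Gzmb, the cytotoxic protease granzyme B, was at -2.17, -0.54 and -0.96. The dendritic cell attractant Xcl1 was at -1.31, -0.83 and -1.14, and the costimulatory receptors Tnfrsf4 and Tnfrsf9 were at -1.65, -0.76 and -0.56, and -1.38, -0.44 and -0.62. In T cells Xcl1 was at -1.40, -2.08 and -0.95, the fatty acid carrier Fabp5 at -1.20, -1.31 and -0.95, and the proteasome subunit Psmb5 at -0.85, -0.62 and -0.72. Higher in T cells of SOX17KO were Fosb, 2.62, 0.72 and 0.74, Fos, 1.40, 1.03 and 0.66, and the collagen-binding integrin chain Itga1, 0.99, 0.69 and 0.83. T cell sums follow the make-up of that class too. Fosb was among the leading genes of a subcluster with 5 Control and 1941 SOX17KO cells in the untimed pair. In regulatory T cells the interleukin-6 receptor gene Il6ra was at 1.09, 1.49 and 1.26. In NK cells and ILCs, granzyme genes differed in direction, as Gzma was at -3.11, -0.53 and -0.57, and Gzme at 3.44, 3.24 and 4.14. Gzme did not pass the expression filter and so was not tested. B cells had the glycolytic enzyme Ldha at -1.13, -1.91 and -1.30. In monocytes and macrophages Isg15, a ubiquitin-like protein induced by interferon, was at -3.19, -0.89 and -0.66, and the acute-phase gene Saa3 at 2.17, 1.22 and 0.91. Dendritic cells had lower Cxcl10, a T cell attractant induced by interferon, at -1.91, -0.85 and -0.55, and lower Isg15, at -1.81, -0.93 and -0.57.

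Of 18 gene lists set before the data were examined, the broadest differences were lower interferon-induced genes and lower MHC class I presentation in SOX17KO. Lists were tested in 7 classes with limma camera at a preset inter-gene correlation of 0.01. The classes overlap, since all cells hold every class and T cells hold the regulatory T cells. Of 117 tests, 47 were called after adjustment (52 at an unadjusted p under 0.05), and 29 without the untimed pair. Other splits that put the libraries of each pair on opposite sides called up to 42 lists. The number of calls thus does not by itself mark the genotype. With an estimated correlation none held, with adjusted p = 0.692 with an estimated correlation for every called list but 2. The directional test of fry called none, and its mixed test called 1, dissociation stress and immediate early genes in regulatory T cells (limma fry adjusted p 0.00261). Type I interferon response genes were lower in all 7 classes. Their median log2 fold changes were -0.70 in all cells, -0.79 in T cells, -0.51 in regulatory T cells, -0.72 in NK cells and ILCs, -1.08 in B cells, -0.57 in monocytes and macrophages, and -0.68 in dendritic cells. The limma adjusted p ranged from 1.83e-07 to 0.0186, against adjusted p = 0.692 with an estimated correlation, and of 12 to 27 members per class, 6 in B cells, a single one in NK cells and ILCs was higher in SOX17KO. Adjusted over the list alone, 1 member fell in regulatory T cells and 3 in B cells, and none over all genes tested. The difference was largest in the untimed pair. In T cells the list's median log2 ratio was -2.27, -0.37 and 0.29 in the untimed, 1-week and 2-week pairs, in monocytes and macrophages -2.49, -0.37 and -0.06, and in dendritic cells -2.31, -0.37 and 0.19. Without the untimed pair the list was no longer called in all cells (limma adjusted p 0.469), T cells (0.530) and regulatory T cells (0.391), was still called lower in NK cells and ILCs (0.00014), monocytes and macrophages (1.07e-06) and dendritic cells (0.0483), and could not be tested in B cells. In T cells of the 3 pairs the interferon-induced gene Rtp4 was at -4.12, -0.11 and 0.63, and in dendritic cells Irf7, a transcription factor that amplifies type I interferon, was at -3.27, -0.60 and 0.17. Dendritic cells of the untimed pair also carried T cell genes, at 1386 CPM (UMI counts scaled to the same total) in Control and 1731 CPM in SOX17KO, against 234 CPM and 73.4 CPM in B cells.

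MHC class I presentation genes, which load peptides for CD8 T cells, were lower in all 7 classes, with 19 or 20 members each. The medians were -0.26 in all cells, -0.16 in T cells, -0.33 in regulatory T cells, -0.27 in NK cells and ILCs, -0.42 in B cells, -0.23 in monocytes and macrophages, and -0.33 in dendritic cells. The limma adjusted p ranged from 1.33e-06 to 0.00303 (adjusted p = 0.692 with an estimated correlation). With adjustment over the list alone, 1 member fell in T cells, 4 in regulatory T cells, 2 in B cells and 4 in dendritic cells. The immunoproteasome subunit Psmb8 in T cells was at -1.13, -0.61 and -0.55 in the 3 pairs, and the activator subunit Psme2 at -2.13, -0.42 and -0.46. Without the untimed pair the limma adjusted p was 0.0625 in T cells and 0.0894 in regulatory T cells, and in T cells it was 0.0505 without the 1-week pair. Interferon-gamma response genes were lower in NK cells and ILCs (median -0.20), B cells (-0.81), monocytes and macrophages (-0.12) and dendritic cells (-0.31), with limma adjusted p from 3.63e-06 to 0.0446 (adjusted p = 0.692 with an estimated correlation; 0 members adjusted over the list alone). The call in monocytes and macrophages was lost without the 1-week pair (0.102) or the 2-week pair (0.116). MHC class II genes were called higher in monocytes and macrophages (median 0.31, limma adjusted p 0.0407) and lower in NK cells and ILCs (-0.23, 0.0282), both with adjusted p = 0.692 with an estimated correlation and 0 members adjusted over the list alone. For monocytes and macrophages the per-pair medians were 1.01, -0.18 and 0.22, where the untimed value compares 159 monocytes of 196 cells in Control with 14 of 54 in SOX17KO, and without the untimed pair the adjusted p was 0.946, and 0.512 in NK cells and ILCs. In NK cells without ILCs the type I interferon, MHC class I and interferon-gamma lists stayed called (limma adjusted p 2.60e-07, 0.000129 and 0.000223) and MHC class II did not (0.235).

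**Figure D2:**
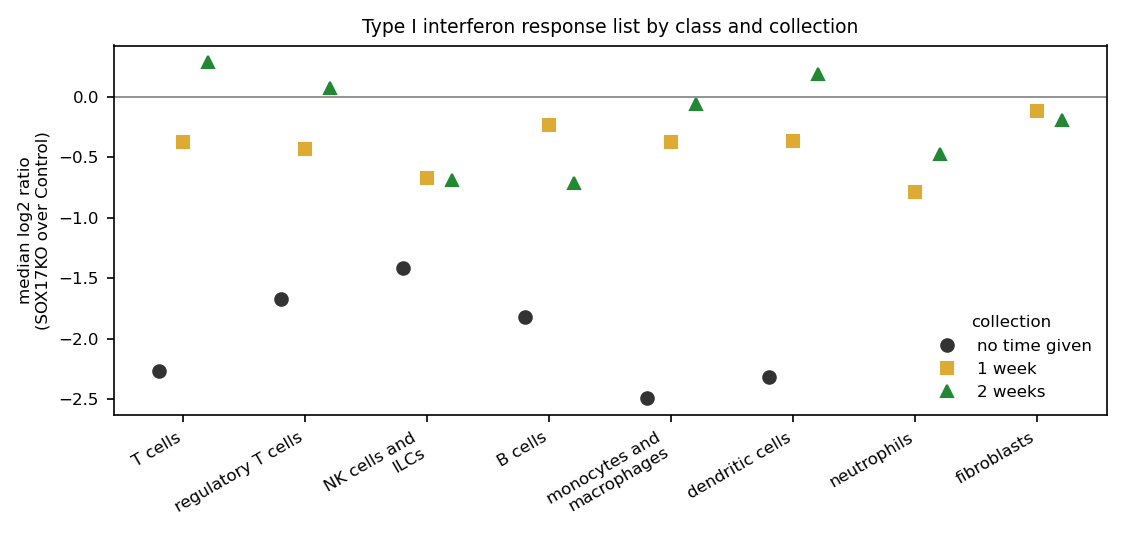
Median log2 ratio (SOX17KO over Control, vertical axis) of the type I interferon response list per class and collection. In T cells the median was -2.27 with no time given, -0.37 at 1 week and 0.29 at 2 weeks.

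Of the lists of lymphocyte function, proliferation, cytotoxic effector, exhaustion and regulatory T effector genes were called lower over all cells, in sums that follow class shares as well as expression. Naive and central memory genes, tissue residency and the type 17 program were not called there (limma adjusted p 0.578, 0.927 and 0.927). Within the cells concerned, the cytotoxic and exhaustion lists were not called in T cells (limma adjusted p 0.217 and 0.180), nor the regulatory T effector list in regulatory T cells (0.205). Proliferation genes had a median of -0.60 in all cells and -0.66 in T cells (limma adjusted p 1.25e-08 and 5.91e-06, adjusted p = 0.692 with an estimated correlation), and in T cells 0 of 24 members had a positive fold change. Adjusted over the list alone, 9 members fell in T cells. Among them, the thymidylate synthase gene Tyms was at -1.30, -0.96 and -0.82 and the cyclin gene Ccna2 at -1.47, -0.71 and -0.62. T cell sums follow the make-up of the class too. A Cd8a-expressing subcluster led by cycling genes held 427 of 2116 Control and 100 of 768 SOX17KO T cells at 2 weeks. Among Cd8a-expressing T cells alone its share was 39.6% and 36.6% at 2 weeks, and 9.06% and 1.85% in the untimed pair. Proliferation was called higher in dendritic cells, with a median of 0.26 (limma adjusted p 0.0184, and 0.812 without the untimed pair). Cytotoxic effector genes were lower in all cells (median -0.51), NK cells and ILCs (-0.19) and dendritic cells (-0.42), with limma adjusted p of 0.00119, 0.00891 and 0.0157 (adjusted p = 0.692 with an estimated correlation, for proliferation in dendritic cells too). The call in NK cells and ILCs was lost without the untimed pair (0.530) or the 1-week pair (0.252), and that in dendritic cells without the 2-week pair (0.106). Other T cell genes were lower there too without passing the edgeR test, Tox at -2.55, -1.18 and -1.61 and Ctla4 at -0.48, -1.86 and -1.17, so that call is not assigned to the dendritic cells themselves here. With adjustment over the list alone, 1 cytotoxic member fell in all cells. Inhibitory receptor and exhaustion genes were lower in all cells, with a median of -0.43 (limma adjusted p 0.00142; 0 members adjusted over the list alone). Regulatory T effector genes were lower in all cells (median -0.55, limma adjusted p 1.18e-05) and in T cells (-0.63, 0.0155), and higher in NK cells and ILCs (0.28, 0.0104). The T cell class holds the regulatory T cells, which were 746 of its 3578 Control and 56 of its 4511 SOX17KO cells in the untimed pair, and within regulatory T cells the list was not called (-0.12, limma adjusted p 0.205). The calls all had adjusted p = 0.692 with an estimated correlation. Adjusted over the list alone, 6 members of the regulatory T list fell in all cells and 3 rose in NK cells and ILCs. The call in T cells was lost without the untimed pair (0.234) or the 1-week pair (0.218), and that in NK cells and ILCs without the untimed pair (0.116). In NK cells without ILCs neither the cytotoxic nor the regulatory T effector list was called (limma adjusted p 0.493 and 0.516). Naive and central memory genes were higher in regulatory T cells and B cells, with medians of 0.34 and 0.31 (limma adjusted p 0.0157 and 0.0196, adjusted p = 0.692 with an estimated correlation). With adjustment over the list alone, 2 members rose in each, and the call in B cells was lost without the 1-week pair (0.102). In regulatory T cells Klf2, a transcription factor of naive T cells, was at 2.39, 2.15 and 0.59; the call was lost without the untimed pair (0.169) or the 2-week pair (0.313). Tissue residency genes were called in no class (lowest limma adjusted p 0.385).

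Dissociation stress and immediate early genes, which respond to handling as well as to stimulation, were higher in T cells (median 0.44) and regulatory T cells (0.20) and lower in B cells (-0.42). Limma adjusted p values were 0.00506, 0.000344 and 2.95e-05 (adjusted p = 0.692 with an estimated correlation), and adjusted over the list alone 5 and 6 members rose and 5 fell. In regulatory T cells Klf4 was at 2.43, 1.38 and 1.91, and Egr1 at 1.03, 1.91 and 1.22. The call in T cells was lost without the untimed pair (0.116) and that in B cells without the 1-week pair (0.182). Hypoxia and glycolysis genes were higher in NK cells and ILCs (median 0.35) and lower in B cells (-0.67), regulatory T cells (-0.17) and monocytes and macrophages (-0.21). Their limma adjusted p values were 0.00105, 0.00807, 0.0407 and 0.0355, with adjusted p = 0.692 with an estimated correlation in the first 3 and 0.796 in the last. Adjusted over the list alone, 3 members rose in NK cells and ILCs and 1 fell in B cells. In NK cells and ILCs the kinase gene Pdk1 was at 0.66, 1.04 and 1.15. Each of these 4 calls was lost when 1 pair was left out: the 2-week pair in NK cells and ILCs (0.107), the 1-week pair in B cells (0.656) and regulatory T cells (0.849), and the untimed pair in monocytes and macrophages (0.0823). Mitochondrially encoded genes, a sign of RNA quality, were higher in NK cells and ILCs (0.29), monocytes and macrophages (0.16) and dendritic cells (0.14). Their limma adjusted p values of 0.00384, 0.00519 and 0.0324 became 0.391, 0.222 and 0.881 without the untimed pair. With an estimated correlation the adjusted p was 0.692, 0.692 and 0.748, and 1 member rose in NK cells and ILCs adjusted over the list alone. Smaller calls were the type 17 cytokine program, higher in NK cells and ILCs (0.67) and lower in dendritic cells (-0.32), chemokines, lower in dendritic cells (-0.27), suppressive and lipid-associated macrophage genes, higher in all cells (0.38), and inflammatory cytokines, higher in NK cells and ILCs (0.32). Their limma adjusted p values were 0.0157, 0.0373, 0.0421, 0.0438 and 0.037, and adjusted p = 0.692 with an estimated correlation for each. With adjustment over the list alone, 2 type 17 members rose in NK cells and ILCs and 2 fell in dendritic cells, with 0 in the others. All 5 were lost without the untimed pair or the 2-week pair, with adjusted p of 0.391, 0.201, 0.433, 0.242 and 0.391 in turn. In NK cells without ILCs hypoxia genes stayed called (limma adjusted p 0.0309), mitochondrially encoded genes (0.0536) and inflammatory cytokines (0.174) did not, and the type 17 list had too few members. Neutrophil maturity and aging genes were called in no class (lowest limma adjusted p 0.122). Test, median and mean had the same sign in all 47 calls.

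The untimed pair was then read class by class, as ratios of CPM in SOX17KO over Control. Cd8a-expressing T cells of SOX17KO had more mRNA of Ifng, the gene of interferon-gamma, at 692 CPM against 283 CPM (ratio 2.45 [2.32, 2.58]). They had less Gzmb, at 91.0 CPM against 731 CPM (0.125 [0.116, 0.133]), at near equal Cd8a (1.01 [0.969, 1.05]). Cd274, which encodes the checkpoint ligand PD-L1, was at 1.82 [1.67, 2.00] and the interferon-gamma receptor gene Ifngr1 at 1.47 [1.42, 1.52]. The nuclear lamin gene Lmna was at 26.5 [19.8, 36.3], the growth factor receptor gene Igf1r at 13.6 [11.2, 16.5], and Ramp3, a partner of the calcitonin receptor-like receptor, at 19.5 [16.0, 23.9]. Galnt18 and Tmprss6 had no UMI in SOX17KO and were at least 700-fold and 115-fold lower at the floor of 3 counts. Glis1 was higher in Control, 186 times [79.1, 575]. CD4 T cells also had more Ifng (1.46 [1.31, 1.62]), more Fosb (5.88 [5.08, 6.83]) and more Lmna (7.83 [6.31, 9.79]), and less Gzmb (0.191 [0.111, 0.310]) and Cxcl10 (0.116 [0.058, 0.209]). The neuropeptide gene Calca had 0 UMIs in Control and was at least 26.8-fold higher. Regulatory T cells had Ifng at 114 CPM against 13.4 CPM in Control (ratio interval [4.99, 14.0], from 23 and 56 UMIs), and Il12rb2, an interleukin-12 receptor chain, at 6.54 [4.19, 9.95]. Their Gzmb was higher, at 1.99 [1.59, 2.46], and the opioid precursor gene Penk was at 0.026 [0.001, 0.145]. Gamma-delta T cells had less Il17a, the interleukin-17A gene (0.221 [0.193, 0.251]), and more Cxcl10 (7.60 [5.44, 10.8]). NK cells and ILCs had less Gzma (0.116 [0.101, 0.133]) and Gzmb (0.251 [0.203, 0.307]) and more Tnfsf11, the RANK ligand gene (from 24 and 200 UMIs, ratio interval [11.8, 28.8]). ILCs were 23 of the 333 Control and 93 of the 169 SOX17KO cells of this class, so these ratios compare different mixtures of cells.

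In the myeloid cells of the untimed pair, monocytes and macrophages of SOX17KO had more H2-Ab1, an MHC class II chain, at 5.03 [4.57, 5.53]. They had more Cd81 (29.3 [16.7, 55.0]), and the alternative-activation gene Retnla, with 0 UMIs in Control, was at least 105-fold higher. Their Cxcl9, a T cell attractant induced by interferon-gamma, was at 154 [40.6, 1309], from 2 UMIs in 2 of 196 Control cells and 52 UMIs in 3 of 54 SOX17KO cells. Vcan was at 0.081 [0.042, 0.142] and Thbs1 at 0.097 [0.079, 0.118]. The interferon-induced Oasl2 had 0 UMIs in SOX17KO and was at least 10.3-fold lower. These ratios rest on 196 and 54 cells, of which macrophages were 0.569% and 0.661% of all cells and monocytes 2.45% and 0.231%. Dendritic cells had less Cd274 (0.249 [0.221, 0.281]), Cxcl10 (0.265 [0.207, 0.337]) and Ifitm1 (0.014 [0.009, 0.020]), and more Lmna (16.4 [13.3, 20.4]). They also carried T cell genes, at 1386 CPM in Control and 1731 CPM in SOX17KO. Lmna was higher in Cd8a-expressing T cells too. Ifitm1 was among the leading genes of a T cell subcluster with 101 Control and 1 SOX17KO cells of this pair. These ratios are therefore not assigned to the dendritic cells themselves here. Type 1 conventional dendritic cells, which cross-present antigen, were 1.45% and 2.36% of cells, type 2 cells 3.03% and 0.777%, and mature regulatory dendritic cells 2.54% and 0.777%. B cells had less of the immediate early gene Egr1 (0.189 [0.134, 0.261]) and less Cd274 (0.539 [0.451, 0.641]). Over all cells of the pair, in sums that follow class shares too, Ifng was at 3.28 [3.18, 3.39], Cd8a at 1.71 [1.66, 1.76] and Gzmb at 0.222 [0.211, 0.233]. The B cell attractant Cxcl13 was at least 124-fold higher and Lyz1, a lysozyme gene of Paneth cells and some macrophages, was at 83.7, from 35 and 2003 UMIs. Cxcl13 was among the leading genes of a fibroblast cluster with 0 Control and 28 SOX17KO cells of this pair. Lyz1 was among those of the unnamed clusters 24 (1 and 283 cells) and 26 (4 and 42 cells). Scaling by TMM moved the ratios of this pair by 0.11 log2 in all cells, 0.17 in T cells, 0.14 in Cd8a-expressing T cells and -0.16 in monocytes and macrophages.

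In the 1-week pair the few T cells, 69 and 129, had more mRNA of some cytokine genes in SOX17KO, while the inflammatory cytokine list was not called in T cells over the 3 pairs (limma adjusted p 0.578). Ifng was at 153 CPM in Control and 2252 CPM in SOX17KO, a ratio of 14.7 [11.4, 19.3]. Ccl4, a chemokine for T cells and monocytes, was at 25.9 [17.1, 41.6], and its relative Ccl3 had 0 UMIs in Control and was at least 82.0-fold higher. The interferon-induced Ifi27l2a was at 0.461 [0.418, 0.509]. NK cells and ILCs had less Gzmb (0.595 [0.555, 0.637]) and more Gzmc (2.65 [2.03, 3.51]). Regulatory T cells had more Klf2 (4.61 [2.32, 10.2]) and less Lgals3, the galectin-3 gene (0.330 [0.192, 0.547]). Monocytes and macrophages, the largest class at this time, differed little in Cxcl9 (1.11 [1.09, 1.13]), Cd274 (0.943 [0.924, 0.964]) and H2-Ab1 (0.861 [0.851, 0.871]). They had somewhat less Cxcl10 (0.803 [0.793, 0.814]) and more of the acute-phase genes Lcn2 (3.20 [2.17, 4.84]) and Wfdc21 (5.65 [3.58, 9.35]). Dendritic cells had less Cxcl10 (0.553 [0.517, 0.591]) and more of the neutrophil attractant Cxcl3 (5.62 [3.13, 11.0]). Neutrophils had less Ccl4 (0.383 [0.366, 0.399]), Ccl2 (0.337 [0.260, 0.436]), Cxcl10 (0.495 [0.466, 0.527]) and Cd274 (0.625 [0.584, 0.669]), with a TMM shift of -0.17 log2. Fibroblasts had less Lgr5, a stem cell receptor gene (0.051 [0.027, 0.088]), and more Saa3 (3.62, from 479 and 2536 UMIs). Over all cells the mast cell protease genes Mcpt1 and Mcpt2 had 0 UMIs in Control and were at least 444-fold and 760-fold higher in SOX17KO, and the interleukin-22 gene Il22 was at 0.027 [0.007, 0.072]. These sums follow class shares too, and mast cells numbered 17 in Control and 40 in SOX17KO.

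In the 2-week pair the Cd8a-expressing T cells differed little in the main effector genes. Ifng was at 319 CPM in Control and 247 CPM in SOX17KO (0.775 [0.708, 0.847]), Gzmb at 0.945 [0.907, 0.985] and Cd274 at 1.28 [1.11, 1.46]. The granzyme gene Gzmf was higher, at 5.04 [4.27, 5.95], and the chemokine gene Ccl1 lower, at 0.179 [0.139, 0.227]. CD4 T cells had more Ero1l, an oxidoreductase gene of the endoplasmic reticulum (3.08 [2.69, 3.52]), Pdk1 (2.58 [1.78, 3.79]) and the protease gene Furin (3.04 [2.77, 3.34]). Regulatory T cells had less Ccl4 (0.083 [0.055, 0.120]). NK cells and ILCs had more Gzmg, another granzyme gene (51.5 [26.9, 113]). Monocytes and macrophages had less Ccl2 (0.427 [0.390, 0.467]) and Ccl7 (0.277 [0.221, 0.344]), which attract monocytes, and less Cxcl9 (0.716 [0.681, 0.754]) and Cxcl10 (0.701 [0.666, 0.737]). They had more of the neutrophil attractants Cxcl3 (4.88 [3.77, 6.39]) and Cxcl5, which had 0 UMIs in Control and was at least 44.9-fold higher. Dendritic cells had less Cxcl9 (0.668 [0.610, 0.730]) and Cxcl10 (0.682 [0.583, 0.797]). Neutrophils had less Cxcl10 (0.511 [0.455, 0.574]) and more of the MHC class II genes H2-Ab1 (8.87 [3.92, 24.8]) and H2-Aa (11.6 [4.81, 36.6]). Their H2-Ab1 rested on 6 Control and 88 SOX17KO UMIs, at 21.4 and 190 CPM. Monocytes and macrophages held it at 3377 and 3852 CPM, and free RNA or doublets as its source in neutrophils were not tested. Fibroblasts had more of the contractile genes Myh11 (30.4 [13.7, 83.9]) and Rgs5 (15.4 [9.90, 25.2]). Control fibroblasts also carried T cell genes at 1789 CPM and SOX17KO fibroblasts at 872 CPM. Over all cells, in sums that follow class shares too, Ifng was at 0.587 [0.557, 0.619], Gzmb at 0.514 [0.498, 0.530], Cd8a at 0.418 [0.396, 0.442] and H2-Ab1 at 1.44 [1.42, 1.46].

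Shares of Cd8a-expressing T cells with a UMI were compared after each cell was thinned to 1000 UMIs. In the untimed pair Ifng was found in 17.6% of 898 Control cells and 33.9% of 3220 SOX17KO cells, against 0.830% and 0.697% of B cells. Gzmb was found in 33.5% and 6.12%, the perforin gene Prf1 in 21.3% and 8.04%, and the inhibitory receptor genes Pdcd1, Havcr2 and Lag3 in 35.2% and 22.3%, 19.3% and 10.9%, and 8.58% and 0.621%. Tox, a transcription factor of exhausted T cells, was found in 449 of 898 Control cells and in 9.75% of SOX17KO cells, and Mki67, a marker of cycling, in 9.13% and 2.58%. At 2 weeks the shares were close, with Ifng in 17.9% and 17.8%, Gzmb in 41.1% and 39.3%, Prf1 in 12.9% and 12.2%, Pdcd1 in 22.4% and 16.3%, Lag3 in 12.4% and 10.4%, Tox in 20.6% and 20.0%, and Mki67 in 23.2% and 21.5%, of 1071 and 270 cells. B cells had these genes in at most 2.91% of cells in the untimed and 2-week libraries. Their median depth before thinning was 3047 and 2472 UMIs in the untimed libraries, against 5149 and 2981 in the Cd8a-expressing cells. At 2 weeks the depths were 3851 and 2984.5 UMIs in B cells against 6275 and 6853. In monocytes and macrophages Cxcl10 was found in 4.62% and 3.85% (untimed), 48.5% and 41.1% (1 week), and 22.3% and 18.5% (2 weeks). H2-Ab1 was found in 22.6% and 71.2%, 64.2% and 60.3%, and 70.1% and 76.9% of them. Cxcl9 was at 33.0% and 31.9% at 1 week and 27.7% and 21.2% at 2 weeks, Arg1, an arginase gene of suppressive macrophages, at 31.2% and 30.1%, and 28.6% and 30.7%, and Nos2, the inducible nitric oxide synthase gene, at 7.07% and 7.28%, and 7.07% and 14.2%. In the untimed pair, SOX17KO minus Control was 2.82 percentage points for Cxcl9, -5.13 for Arg1 and -0.51 for Nos2. Cd8a-expressing T cells, taken as background, had Cxcl10 in 0.668% [0.246, 1.45] and 2.11% [1.64, 2.67] in the untimed pair and in 1.21% and 0.370% at 2 weeks. The untimed share of monocytes and macrophages lay above it in Control (4.62% [2.13, 8.58]) and was not set apart from it in SOX17KO (3.85% [0.469, 13.2], 2 of 52 cells). Monocytes and macrophages had median depths of 6674 and 3758.5, 5884 and 6769, and 3992.5 and 5366 UMIs. None of the 16 readouts could fall under 0.25 in the two-sided exact sign-flip permutation test. Tox and Cxcl10 reached 0.25 (adjusted p = 1), each lower in SOX17KO in 3 of 3 pairs, with Tox at 1 week resting on 4 and 15 cells.

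**Figure D3:**
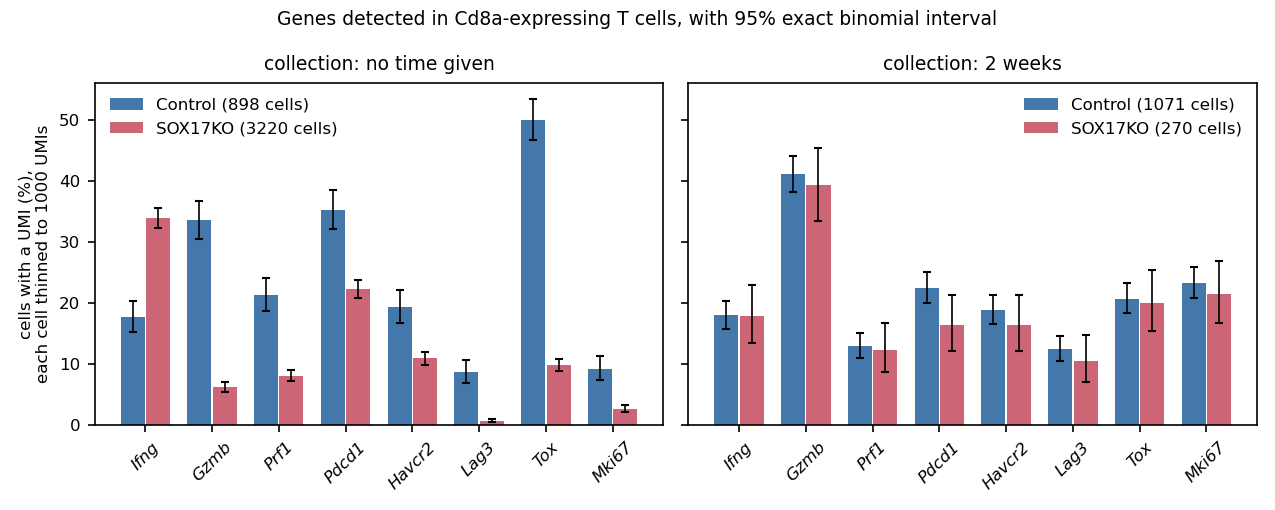
Percent of Cd8a-expressing T cells with at least 1 UMI of each gene (vertical axis) after thinning to 1000 UMIs per cell, Control blue and SOX17KO red, with 95% exact binomial intervals. With no time given, Ifng was found in 17.6% and 33.9% of cells and Gzmb in 33.5% and 6.12%; at 2 weeks both were close.

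Both genotypes had more T cells and fewer monocytes and macrophages at 2 weeks than at 1 week. T cells were 1.32% of Control cells at 1 week and 46.2% at 2 weeks, and 1.88% and 26.2% of SOX17KO cells. Monocytes and macrophages were 56.2% and 20.2% in Control and 55.4% and 27.2% in SOX17KO. Over all cells, the 2-week to 1-week ratio of Cd8a was 42.0 [36.3, 49.0] in Control and 19.7 [17.1, 22.7] in SOX17KO. Ifng was at 4.36 [4.11, 4.62] and 1.99 [1.88, 2.11], up to 196 CPM in Control and from 57.9 to 115 CPM in SOX17KO, in sums that follow the share of T cells. Within T cells Ifng was at 2.11 [1.63, 2.76] in Control and 0.129 [0.120, 0.139] in SOX17KO, from 69 and 129 cells at 1 week, and within NK cells and ILCs at 0.378 [0.319, 0.447] and 0.411 [0.350, 0.481]. Over all cells the interferon-induced gene Isg15 was at 0.127 in Control and 0.207 in SOX17KO, Cxcl9 at 0.278 and 0.310, and Cxcl10 at 0.145 and 0.191. Within monocytes and macrophages Isg15 was at 0.288 [0.269, 0.308] and 0.339 [0.313, 0.366], Cxcl10 at 0.408 [0.394, 0.422] and 0.356 [0.342, 0.370], and Cxcl9 at 0.849 [0.818, 0.881] and 0.549 [0.528, 0.571]. H2-Ab1 in that class was at 1.29 [1.26, 1.31] and 1.71 [1.68, 1.74], and Spp1, the osteopontin gene, at 0.482 [0.441, 0.526] and 0.184 [0.165, 0.205]. The difference between the genotypes in these changes was not tested.

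Barcodes that carried genes of a myeloid or stromal cell often carried T cell genes as well in the untimed SOX17KO library. Over all barcodes, T cells included, 82.5% there and 63.1% in the untimed Control library had at least 5 UMIs of T cell genes. The values were 7.43% and 5.99% in Control and SOX17KO at 1 week, and 50.7% and 32.0% at 2 weeks. Of barcodes with at least 10 UMIs of macrophage genes, 75.5% [69.9, 80.4] also had at least 5 UMIs of T cell genes, against 44.4% in the untimed Control library. In SOX17KO this was 44.7% outside the unnamed cluster 24, which held 159 of these 273 barcodes. B cell barcodes had 25.5% [21.4, 29.9] in SOX17KO, the lowest of the cell types there, and 30.3% in Control. The other types in SOX17KO had 52.5% to 71.5%. At 1 week the macrophage shares were 8.90% and 6.01%, and at 2 weeks 18.4% and 16.3%. Sox17 itself had 3 to 20 UMIs per library, which tests nothing about the knockout since the sort was meant to leave tumour cells out. Ddx3y, a gene of the Y chromosome, was at 103 to 224 CPM in all 6 libraries. Xist, expressed from the inactive X chromosome, had 307 UMIs (8.07 CPM) in the untimed Control library and 1 to 4 UMIs in each of the others.

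**Figure D4:**
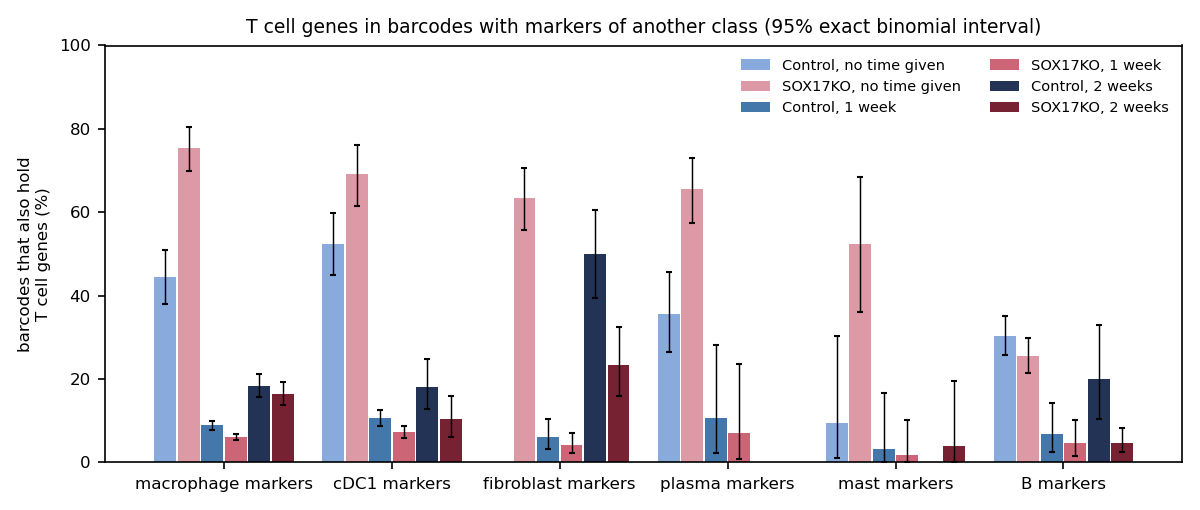
Percent of barcodes with at least 10 UMIs of a cell type's genes that also had at least 5 UMIs of T cell genes (vertical axis), per library, with 95% exact binomial intervals. In the SOX17KO library with no time given, macrophage barcodes were at 75.5% and B cell barcodes at 25.5%.

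Positions of the genes named most often, on mouse genome build mm10, are as follows. Sox17 (ENSMUSG00000025902) lies on chromosome 1 from 4490931 to 4497354, Fos (ENSMUSG00000021250) on chromosome 12 from 85473890 to 85477273, and Pkp4 (ENSMUSG00000026991) and Bmyc (ENSMUSG00000049086) on chromosome 2 from 59160850 to 59355208 and from 25706739 to 25707721. Chromosome 5 holds Areg (ENSMUSG00000029378, 91139599 to 91148432), Cxcl9 (ENSMUSG00000029417, 92321347 to 92328079) and Cxcl10 (ENSMUSG00000034855, 92346638 to 92348889). Chromosome 10 holds Ifngr1 (ENSMUSG00000020009, 19591949 to 19610229) and Ifng (ENSMUSG00000055170, 118441046 to 118445892), and chromosome 4 Tox (ENSMUSG00000041272, 6686353 to 6991557) and Isg15 (ENSMUSG00000035692, 156199424 to 156200818). Cd8a (ENSMUSG00000053977) lies on chromosome 6 from 71373427 to 71379173, Gzmb (ENSMUSG00000015437) on 14 from 56258838 to 56262260, H2-Ab1 (ENSMUSG00000073421) on 17 from 34257689 to 34269419, and Cd274 (ENSMUSG00000016496) on 19 from 29367455 to 29388095.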

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

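Every test of an explanation in this part was chosen after the result it addresses had been seen, and differences between the pairs were not tested, since each pair holds 1 library per genotype. Class shares stood out where the pairs moved in opposite directions, and are given as SOX17KO minus Control in percentage points. T cells differed by 19.5 points in the untimed pair, 0.564 at 1 week and -20.0 at 2 weeks. Cd8a-expressing T cells differed by 41.8 points in the untimed pair and -14.2 at 2 weeks. Gamma-delta T cells differed by -2.06 points in the untimed pair and 0.362 at 1 week. NK cells and ILCs differed by -2.33 points in the untimed pair and 1.55 at 2 weeks. Neutrophils differed by -5.31 points in the untimed pair, 5.78 at 1 week and 3.74 at 2 weeks. Monocytes and macrophages differed by -2.12 points in the untimed pair and 6.99 at 2 weeks. Shares of 1 sum trade against each other, so these are not independent results. Outside the named classes, a cluster closest to macrophages (cluster 24) made 4.68% of the untimed SOX17KO cells and 0.015% of the untimed Control cells. A second such cluster (cluster 26) made 0.694% of the untimed SOX17KO cells and 0.062% of the Control cells, and 1.94% and 0.523% at 2 weeks.

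Type I interferon genes were lower in every tested class of the untimed SOX17KO library, at 371 CPM against 1498 CPM in T cells, 966 CPM against 4530 CPM in monocytes and macrophages, and 294 CPM against 1526 CPM in dendritic cells. Free RNA in the Control library was set at the level that T cell genes in dendritic cells allow (36.6% of the library's level). The excess was 2.76 times that level in regulatory T cells, 5.965 in monocytes and macrophages and 2.06 in dendritic cells. This does not exclude free RNA, since these classes were grouped by their values. The level also takes free RNA at the mean of all cells (1631 CPM), while neutrophils held 3968 CPM. In T cells, NK cells and ILCs, and B cells free RNA cannot be told apart either. Their excess was 1.89, 0.489 and 0.672 times that level, and the rule asked for over 2 times. A first version of this limit, without dendritic cells (7.28%, excess at least 2.46 times), was widened, and the classes were parted into these groups, after its values were seen. The same genotype effect in every collection cannot be told apart, because at 2 weeks the list was higher in SOX17KO in T cells by 0.285 log2 but lower in NK cells and ILCs (-0.69), in single libraries. A first rule of this test used T cells alone and argued against the same effect, and it was changed to all 6 classes after its value was seen. Time, a batch difference of the untimed pair, a change of cell types within a class (monocytes, with Cxcl10, Slfn5 and Trim30c among their leading genes, were 159 of the 196 Control and 14 of the 54 SOX17KO monocytes and macrophages) or the near absence of plasmacytoid dendritic cells, a class that 3 alternatives did not name, may each contribute and stay untested.

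Cluster 24 held 283 cells of the untimed SOX17KO library with genes of macrophages (Lyz1, Retnla, Gpnmb, Ms4a7) and of T cells, the latter at 3389 CPM, and with a median of 9541 UMIs against 2916 in T cells and 3647.5 in monocytes and macrophages. Chance doublets cannot be told apart, since the 75.5% of macrophage barcodes with T cell genes lay above the 25.5% of B cell barcodes but not clear of other types such as type 1 conventional dendritic cells (69.1%), and the cluster's depth above either type does not speak against doublets. Free RNA cannot be told apart either, because T cell genes lay at 46.2 times their level in B cells but at 1.96 times their level in dendritic cells, and fibroblasts, left out of this test, held them at 2833 CPM. T cell genes made 58.8% of a T cell profile, where 1 T cell beside 1 macrophage of median depth would give 44.4%. The rule could reject contact only for a share well below 44.4%, so a higher share could not fail it. The cluster's median depth was also higher than the 2 medians of this model together. Macrophages in contact with T cells stay a possible explanation, and the test does not separate contact from doublets or from uptake of T cells. The tests on doublets and free RNA were first set against B cells alone, where they argued against both, and were changed after their values were seen, as were the limits of 10 and 5 UMIs.

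Fos was higher in regulatory T cells of each SOX17KO library, by 1.61, 1.78 and 1.97 log2. Handling of whole libraries during dissociation cannot be told apart, since the median Fos ratio over 24 other classes and pairs was 0.248, with 15 above 0, but Cd8a-expressing T cells (2.13) and mast cells (1.77) of the untimed pair lay above its regulatory T cells. In the 1-week and 2-week pairs the other classes lay lower, up to 0.62 and 1.31. This test was first made on the dissociation list in B cells and then on Fos without Cd8a-expressing T cells and some smaller classes, and was changed after these values were seen. A response of regulatory T cells to the SOX17KO tumours may be involved and was not tested apart from handling, with 45 to 124 Fos UMIs in each SOX17KO library.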

How the results depend on the processing

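Each pair is 1 library per genotype, so most share differences of 1 pair have narrow counting intervals and no replicate spread, and the gene test rests on 2 residual degrees of freedom. Depth limited regulatory T cells at 1 week (24 and 35 cells), Cd8a-expressing T cells at 1 week (4 and 15) and monocytes and macrophages of the untimed SOX17KO library (54). Counting unnamed clusters with their closest class, the denominator without fibroblasts and unnamed clusters, the test of 2 pairs of Cd8a-expressing T cells that of NK cells alone (genes and lists) and the hypoxia list with Ero1l and Aldoa were chosen after seeing the data. Of the alternatives other than leaving out a pair, 123 of 130 mean share differences, 326 of 357 share differences of 1 pair, 55 of 76 counts of genes, 70 of 99 fold changes of called genes and 25 of 32 readouts stayed the same. Of 239 gene ratios, 212 stayed within their interval with TMM totals and 27 moved. Where a value changed, the cause was not tested, apart from what an alternative does by its own construction.

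Share differences are given as log2 odds, SOX17KO minus Control. Without doublet removal the mean log2 odds difference of T cells turned from 0.17 to -0.0205 and the mean log2 odds difference of CD4 T cells from 0.0023 to -0.0443, and the untimed values became 0.74 for T cells and 3.12 for Cd8a-expressing T cells. With the automatic doublet threshold the untimed values were 0.85 for T cells, 2.29 for Cd8a-expressing T cells and -2.16 for dendritic cells. At least 500 genes per cell gave 1.13 for untimed T cells, 1.26 for 2-week neutrophils and -1.16 for untimed monocytes and macrophages. At resolution 2 untimed dendritic cells were at -1.33. With each collection clustered alone, the mean for monocytes and macrophages turned from -0.42 to 0.29 and their untimed value from -1.78 to 0.23, with -0.25 at 1 week and 0.88 at 2 weeks. Untimed T cells were then at 1.06, untimed Cd8a-expressing T cells at 2.40, 1-week NK cells and ILCs at -0.40 and untimed dendritic cells at -1.37. With T cells as the denominator, Cd8a-expressing T cells were at 3.11 (untimed) and -0.91 (2 weeks), the share of regulatory T cells in the untimed pair at -4.38 and untimed gamma-delta T cells at -1.24. Under it CD4 T cells turned in the mean (-0.0281) and the untimed pair (from 0.26 to -0.24) and moved from -0.06 to 0.98 at 2 weeks, and regulatory T cells at 2 weeks turned from -0.67 to 0.18. Without neutrophils in the denominator untimed T cells were at 1.08 and 1-week monocytes and macrophages at 0.18. Without fibroblasts and unnamed clusters in it, untimed T cells were at 1.39, the mean for CD4 T cells turned to -0.0457, and 1-week monocytes and macrophages were at -0.39. With unnamed clusters counted in their closest class, plasma cells turned in the mean (from 1.47 to -1.05) and the untimed pair (from 0.99 to -2.06), as did monocytes and macrophages (mean 0.26, untimed 0.61), with -0.33 for the latter at 1 week and 0.72 for neutrophils at 1 week.

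Counts of genes called were 39 in all cells, 6 in T cells and 1 in dendritic cells with DESeq2, and 6 in regulatory T cells and 10 in B cells with limma-voom. RLE size factors gave 3 in NK cells and ILCs, and NK cells alone gave 0. Without the expression filter 315 genes were called in T cells, 41 in regulatory T cells, 183 in NK cells and ILCs, 33 in B cells, 91 in monocytes and macrophages and 135 in dendritic cells. Without a collection term the counts were 0 in regulatory T cells and 0 in NK cells and ILCs. For regulatory T cells the count was 1 with at least 500 genes, 0 with at most 5% mitochondrial UMIs, 5 with the automatic doublet threshold and 5 at resolution 2. For NK cells and ILCs it was 17 with at most 5% mitochondrial UMIs and 0 with each collection clustered alone. With an estimated correlation 0 gene lists were called, and 0 with fry, against 47 with Ero1l and Aldoa in the hypoxia list and 40 with NK cells alone in place of NK cells and ILCs. Mean readout differences are in percentage points. Without thinning the Gzmb readout in Cd8a-expressing T cells turned from 5.81 to -7.43, the Pdcd1 readout in Cd8a-expressing T cells from 0.322 to -6.20 and the Mki67 readout in Cd8a-expressing T cells from 8.34 to -16.4. Thinned to 500 UMIs these 3 turned to -3.06, -3.24 and -15.4, and the Cxcl9 readout in monocytes and macrophages turned from -1.59 to 0.071.

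Leaving out 1 pair at a time gave mean log2 odds from -0.38 to 0.89 for T cells, -0.0921 to 2.16 for Cd8a-expressing T cells, -0.12 to 0.10 for CD4 T cells, -0.54 to 0.74 for gamma-delta T cells, -0.42 to 0.23 for NK cells and ILCs, -1.88 to 1.10 for neutrophils and -0.91 to 0.26 for monocytes and macrophages. Genes called ranged from 0 to 20 in all cells (20 without the untimed pair), 0 to 114 in T cells (114 without the 2-week pair), 5 to 23 in regulatory T cells, 0 to 34 in NK cells and ILCs, 0 to 53 in B cells, 0 to 17 in monocytes and macrophages and 0 to 1 in dendritic cells. These fits keep 1 residual degree of freedom. Gene lists called ranged from 29 to 54. Readouts ranged from -14.6 to 22.4 points for Gzmb, -9.52 to 6.94 for Pdcd1, -5.43 to 2.10 for Havcr2, -4.16 to 15.8 for Mki67, -3.80 to 0.884 for Cxcl9, -3.10 to 0.522 for Arg1, -0.321 to 0.202 for Spp1 and -0.151 to 3.65 for Nos2. Of 26 fold changes of called genes, 11 stayed past the threshold and 15 did not. With each collection clustered alone no Cd8a-expressing, CD4 or B cells were named at 1 week, no gamma-delta T cells in the untimed pair, no plasma cells at 1 or 2 weeks and no plasmacytoid dendritic cells. Plasmacytoid dendritic cells were also not named without doublet removal or with the automatic threshold, and B cells could not be tested with at most 5% mitochondrial UMIs or with each collection clustered alone.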

Other observations

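The tests of other splits in this part were chosen after the results had been seen, and the values in this paragraph come from comparisons the report did not describe. Several clusters differed in share between libraries or collections. A cluster closest to plasma cells but with few UMIs per cell (median 768) and with epithelial keratin genes among its leading genes made 9.45% of the untimed Control cells and 0.975% of the untimed SOX17KO cells, and 0.219% to 1.11% of the other libraries. A cluster with genes of macrophages and NK cells made 5.49% and 2.84% of Control and SOX17KO cells at 1 week and 1.77% and 1.88% at 2 weeks, and one of neutrophils and monocytes made 3.05% and 1.71% at 1 week. A cluster closest to macrophages, with a median of 1305 UMIs, made 10.4% and 9.20% at 1 week and 6.89% and 5.97% at 2 weeks. A T cell subcluster with a median of 15717.5 UMIs, and with the leading genes Galnt18 and Glis1 of untimed Control T cells, held 340 untimed Control cells and 5 untimed SOX17KO cells.

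T cell genes were found in other barcodes of the untimed SOX17KO library beside those of macrophages. Over all barcodes of that library, T cells included, 82.5% carried them. They were carried by 69.1% of barcodes with genes of type 1 conventional dendritic cells, 63.4% with fibroblast genes, 65.6% with plasma cell genes and 52.5% with mast cell genes, against 25.5% with B cell genes. This was not confined to SOX17KO, since barcodes with genes of mature regulatory dendritic cells carried them in 79.0% of the Control and 71.5% of the SOX17KO library of that pair. In the untimed pair CD4 T cells of SOX17KO lay largely in a subcluster with the type 2 cytokine genes Il4, Il5 and Il13 among its leading genes (574 SOX17KO and 37 Control cells), and those of Control in a subcluster led by S1pr1 and Il6ra (351 Control and 33 SOX17KO cells).

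The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 0 genes in all cells, where the highest other split called 38, and all 10 splits gave as many as the real one. In T cells the real split called 0 and the highest other 952, in B cells 0 and 4, in monocytes and macrophages 0 and 177, and in dendritic cells 0 and 924, again with all 10 at least as high. In regulatory T cells the real split called 3 genes and the highest other 47, and 3 of 10 splits called as many. NK cells and ILCs had 6 genes in the real split and 362 in the highest other, and 3 of 10 splits called as many. The gene lists called numbered 47 in the real split and 62 in the highest other, with 3 of 10 as high. Where the real split called 0 genes, all 10 reach it by necessity, so these counts say nothing about genotype. In 6 of the 10 splits both libraries of a collection stand on the same side, which breaks the pairing of the real comparison, and the highest counts above came from these, except in B cells. What drives those counts was not tested. The 3 other splits that part each pair called at most 4 genes in B cells, 1 in regulatory T cells and 0 in the other classes, and at most 42 lists.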
